A study of Homo sapiens with 4 samples.

How the data were processed

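The 4 RNA-seq libraries of the CTCL line Hut78 came from cells with a scrambled hairpin RNA (sh0 group, n = 2) and from cells with a hairpin RNA against IKZF2 (shIKZF2 group, n = 2). The labels' protocols describe lentiviral delivery, culture of stable lines and a column-based RNA extraction. Their extraction text also speaks of skin biopsies, although every sample is labelled as the cell line. The libraries were matched to groups by column name alone: con and sh0 to the sh0 group, and sh1 and sh4 to the shIKZF2 group. The labels do not say whether con carried a hairpin vector, or whether sh1 and sh4 are different hairpins. The names give no replicate number, and although the series calls the libraries biological replicates, nothing says that they came from separate cultures.

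The authors deposited FPKM values, read numbers scaled to exon length and library total, in a single table with gene symbols, gene types, positions and GO annotation. The submitters' processing notes name the genome build hg38 and the tools HISAT2 2.1.0 and Bowtie2 2.2.3, with no role for either. The counter, the annotation release, strand use and whether reads or read pairs were counted are not given in the sources used here, so antisense and overlapping genes are uncertain. The tests fixed before the data were examined assumed read counts. Since the file holds FPKM, the main test became the one fixed for that case: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), for the 12101 genes with a mean of 1 FPKM or more in either group, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. A fold change on that scale understates the change of low genes. The filter on values and the pseudocount of 1 were part of that design.

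The low values showed the depth. Value times exon length fell on whole multiples of 1 step per library for 83.2% to 84.7% of low values of single-transcript genes (tolerance 0.02 reads, GENCODE lengths), which gave the library totals, 16292016 to 17748055 reads. With these totals 58.5% of 27243 genes gave whole reads with the annotated exon length and 41.5% with a length found from the values. The recovered reads were used in an added test, chosen after seeing the file: limma-voom with median-of-ratios factors, for the 15045 genes with 10 or more reads in at least 2 libraries. It is called the read-based test. The recovered totals cover reads assigned to genes. The SE of the read-based test rests on the spread between libraries of a group, pooled in part across genes.

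Gene lists, 44 in number, and the rule for named genes were fixed before the data were examined. Lists with 5 or more tested genes were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, and adjusted over all lists. GO terms of 15 to 300 tested genes were treated likewise. The rule names IKZF2, then the 12 largest rises and 12 largest falls among protein-coding genes that pass, reach 5 CPM or FPKM in the higher group and do not overlap between groups, and up to 4 members per list with the smallest adjusted p (the 2 most abundant for markers of other cell types and RNA quality). As no gene passed the main test, the rises and falls were taken by the same rule from the read-based test. Other genes that the text names were chosen after their values were seen. Some of the genes that the rule names are not reported here.

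Both tests were tested on simulated reads for the real genes, with 200 changed genes. For a simulated shIKZF2 against sh0 comparison, the test on values called 83.7% of 49 genes changed 1.5-fold and 100% of 47 changed 2-fold among 11597 genes tested. The read-based test called 96% of 50 and 100% of 50 among 14781. Of the unchanged genes 25 and 27 were called. At most 200 changed genes could be called beside them, so in both tests the false share of the calls exceeded the threshold of 0.05. The calls of the read-based test on the real data may likewise hold more false ones than that threshold allows. With nothing changed the test on values called 0 genes and the read-based test 1. The simulated spread was taken from the differences between replicate libraries and varied between genes as in the read-based fit (prior degrees of freedom 10.1). In the test on the real values the spread varied more from gene to gene (prior degrees of freedom 3.06). That setting was not simulated, so the shares of changed genes called may be too high for it. Replicates differed by more than sampling noise, so that no library was counted as a duplicate. The chi-square per degree of freedom over genes with 50 or more reads was 4.48 for con against sh0 and 6.22 for sh1 against sh4. By this measure sh4 lay nearly as close to con (7.08) and sh0 (6.83) as to sh1, while sh1 lay farther from con (14.5) and sh0 (13.6). Alternatives covered the pseudocount, the filters, the scaling factors, a fold change threshold, a correction for GC content and length, and each library left out. Count-based tests on deposited counts and a replicate block were planned and not run, since the file holds neither counts nor replicate numbers. Tables and figures were made with the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.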

Results

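Hut78 is a T cell line from the blood of a patient with Sézary syndrome, the leukaemic form of cutaneous T cell lymphoma (CTCL). The cells had received lentiviral vectors that express either a scrambled short hairpin RNA (the sh0 group) or a hairpin RNA against IKZF2 (the shIKZF2 group), and each group had 2 RNA-seq libraries. IKZF2 encodes Helios, a zinc finger transcription factor of the Ikaros family. In the deposited table the libraries are named con and sh0, placed here in the sh0 group, and sh1 and sh4, placed here in the shIKZF2 group. Nothing in the labels says which culture or hairpin each name stands for, so p-values measure the spread between these libraries. The table gave FPKM for 27243 genes, and library totals recovered from the values were 16292016 reads (con), 16415335 (sh0), 17748055 (sh1) and 17416754 (sh4). Genes listed at 0 made up between 15.5% (sh1) and 18.4% (con) of the table.

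The first comparison asked how far the knockdown lowered its target. IKZF2 (ENSG00000030419, chromosome 2, 212999691 to 213152427, hg38) stood at 28.5 ± 1.89 FPKM in the sh0 group and 19.1 ± 0.813 FPKM in the shIKZF2 group (mean ± SD, n = 2 each). Both shIKZF2 libraries, at 18.5 (sh1) and 19.7 (sh4), lay below both control libraries, at 27.2 (con) and 29.9 (sh0). These values rest on 4029 to 6003 reads per library. In limma's test on log2(FPKM + 1) the difference was -0.55 ± 0.07 (SE), with an adjusted p of 0.166, which misses the threshold. In the read-based test, limma-voom on the recovered reads, IKZF2 fell by 0.60 ± 0.06 (SE) on the log2 scale, with an adjusted p of 0.00429, the smallest of all genes tested. That change is 0.659 times the control level. None of the other 4 family members passed either test. IKZF1 (Ikaros) was at 16.0 FPKM against 17.2, IKZF3 (Aiolos) at 11.9 against 10.7, and the read-based adjusted p-values were 0.62 and 0.30.

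**Figure D1:**
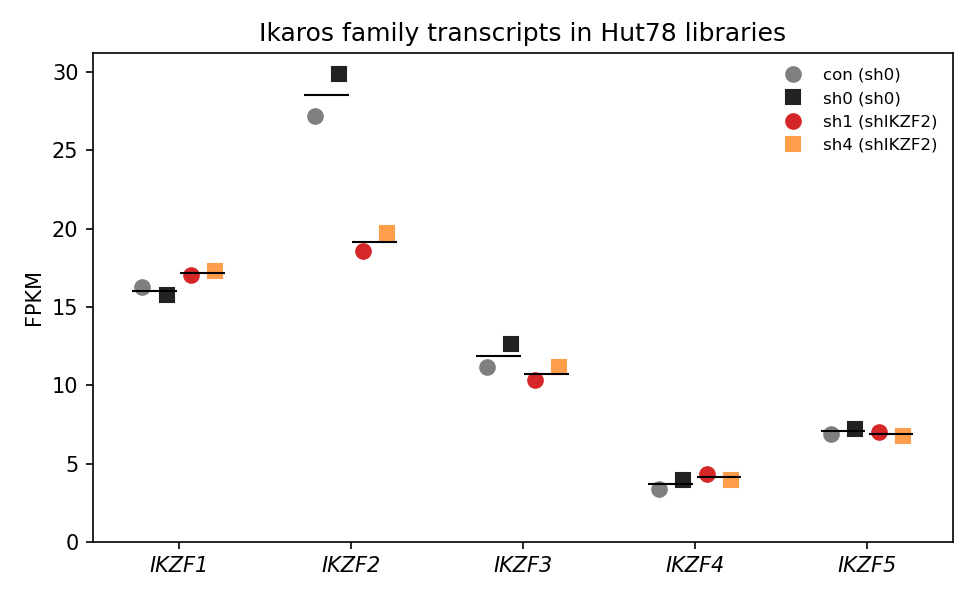
FPKM of the 5 Ikaros family genes in each of the 4 libraries, with points for libraries and bars for the mean of each group of 2. IKZF2 lies at 27.2 and 29.9 FPKM in the sh0 group and at 18.5 and 19.7 in the shIKZF2 group, while the groups of the other genes lie close together.

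The second comparison asked which other transcripts differed after IKZF2 knockdown. In the read-based test CTTN, which encodes the actin-binding protein cortactin, and CCND1, which encodes cyclin D1, rose 5.38-fold and 3.85-fold from low levels. Of 13 MHC class II genes 6 rose (1 without the sh0 library), HLA-DRA among them, from 97.1 ± 16.7 to 173 ± 27.4 FPKM (mean ± SD, n = 2 each). Among the transcripts that fell were LTB (lymphotoxin beta), IL10, the prostaglandin D2 receptor PTGDR2 and the activating receptor NCR3. With fixed gene lists, MHC class II, interferon-stimulated and mitochondrially encoded transcripts were higher as groups, and ribosomal protein, oxidative phosphorylation, G2/M phase and several T cell lists were lower. None of these list calls held with an estimated correlation (adjusted p = 0.681 with an estimated correlation for each). Without the sh0 library CCND1, IL10 and PTGDR2 did not pass, although their log2 changes were close to those with all libraries. They were 1.94, -0.69 and -1.05 without it, and 1.94, -0.72 and -1.09 with it. With 1 library in a group, a lost call need not mean a smaller change. The interferon, mitochondrial, T cell receptor and Th1 lists also ended without sh0, at medians of 0.06, 0.08, -0.05 and -0.15 on the values. With all libraries these medians were 0.09, 0.18, -0.07 and -0.14. Without sh1 the interferon, mitochondrial and T cell receptor lists ended, and without con or without sh4 the T cell receptor and Th1 lists.

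On the deposited values, limma's test passed 0 of 12101 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.166. At an unadjusted p under 0.05 there were 1835 genes, 1028 higher and 807 lower, where chance alone gives 605. The read-based test passed 388 of 15045 genes, 187 higher and 201 lower in shIKZF2, with 2407 at an unadjusted p under 0.05. Of the 388 genes, 376 were also tested on the values, where all 376 had the same direction and an unadjusted p under 0.05. Both tests use the same libraries, and in all 388 the groups did not overlap, so the shared direction was fixed in advance. The median absolute log2 change of the 388 was 0.50, and 36 changed at least 2-fold. The read-based count was 177 without con, 73 without sh0, 328 without sh1 and 1308 without sh4, and it was 0 with no filter on low counts or with a test against a fold change of 1.5. With each library left out in turn, 53 of the 388 passed every time. Rises and falls of single genes are given by the read-based test unless another test is named.

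CTTN was at 0.601 and 0.657 FPKM in con and sh0, and at 4.54 and 2.63 in sh1 and sh4 (log2 change 2.43 ± 0.30 SE, adjusted p = 0.00444). CCND1, a driver of the G1 to S transition, was at 0.915 and 0.921 FPKM in the controls and at 4.84 and 2.68 after knockdown (1.94 ± 0.30 SE, adjusted p = 0.0086). The other genes named by rule as the largest rises ranged from a log2 change of 1.11 to 1.99. They included the sulfotransferase gene CHST15, the neurotrophin receptor gene NTRK2, CSF2, which encodes GM-CSF, the cytidine deaminase gene APOBEC3B, IFIT2, PRAM1, PLXNB1, NRP2 and PON2. CSF2 went from 2.56 ± 0.316 to 7.42 ± 1.74 FPKM, and PON2, the most abundant of these genes, was at 7.90 and 8.86 FPKM in the controls against 22.0 and 15.2. NTRK2, PLXNB1 and NRP2 lay under 1 FPKM in all 4 libraries and did not enter the test on the values. Without the sh0 library, CHST15, CCND1, NTRK2, CSF2, IFIT2, PRAM1, PLXNB1 and NRP2 no longer passed. The log2 change of NRP2 went from 1.15 to 0.64 there. Those of NTRK2, IFIT2 and PLXNB1 went from 1.51, 1.26 and 1.18 to 1.27, 1.17 and 1.03. CCND1 stayed at 1.94, and CHST15, CSF2 and PRAM1 went up, from 1.99, 1.48 and 1.23 to 2.09, 1.60 and 1.32. Without con CHST15, CSF2, PRAM1 and PLXNB1 did not pass, with adjusted p-values from 0.0559 to 0.0876.

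The largest falls were smaller, from a log2 change of -0.86 to -1.16. FAM81A and PTGDR2 led them, and PTGDR2, a receptor typical of Th2 cells, went from 3.85 ± 0.205 to 1.85 ± 0.262 FPKM (mean ± SD, n = 2 each; -1.09 ± 0.17 SE, adjusted p = 0.00952). GCH1, which encodes the first enzyme of tetrahydrobiopterin synthesis, and PRKCH, which encodes protein kinase C eta, fell by 0.96 and 0.92 on the log2 scale. LGALS9C, KBTBD8, ASCL4, RGL4, DBT, ATP6V1C1, ADGRG5 and PTBP3 made up the rest. PTBP3, an RNA-binding protein gene and the most abundant of the 12, went from 50.3 and 48.0 FPKM to 23.5 and 32.3. LGALS9C and APOBEC3B have near-identical relatives in the genome, so that reads may have been divided between copies, and their values are uncertain. Without the sh0 library FAM81A, PTGDR2, LGALS9C, GCH1, PRKCH, KBTBD8, RGL4 and ADGRG5 no longer passed. The log2 changes of FAM81A, PTGDR2, LGALS9C and RGL4 were -1.11, -1.05, -0.89 and -0.92 there. With all libraries they were -1.16, -1.09, -1.03 and -0.89. ASCL4, FAM81A and RGL4 did not pass without con (0.0601 to 0.126), nor FAM81A and RGL4 without sh1 (0.142 and 0.178), where the log2 changes of GCH1, PRKCH and RGL4 went to -0.56, -0.56 and -0.58.

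**Figure D2:**
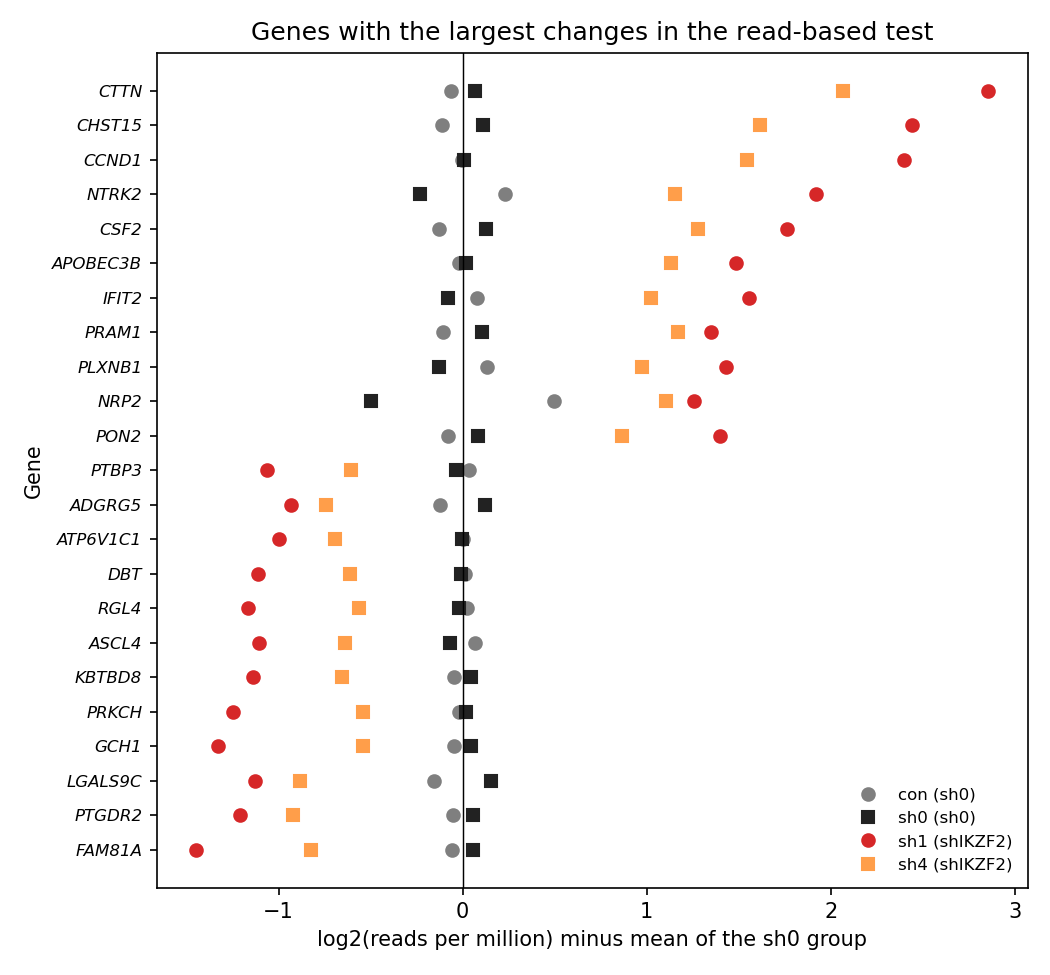
Read level of the genes named here as the largest rises and the largest falls in the read-based test, as log2 CPM (reads scaled to the library total) minus the mean of the sh0 group, 1 point per library. For each gene both shIKZF2 libraries lie on the same side of both sh0 libraries, which the rule that named the genes required. The sh1 library lies farther out than sh4.

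MHC class II genes, whose products present peptides to CD4 T cells, formed the group with the largest shift. Of 13 members tested on reads, 6 rose and 0 fell: HLA-DRA, HLA-DPA1, HLA-DPB1, HLA-DMA, the invariant chain gene CD74 and CIITA, the transcriptional coactivator of these genes. The count was 8 higher and 1 lower adjusted over the list alone. CIITA was at 3.60 and 3.75 FPKM in the controls and at 6.67 and 5.12 in the shIKZF2 libraries, and CD74 was at 286 and 245 FPKM in the controls and at 384 and 333. HLA-DRB1 (3.44 against 6.01 FPKM) did not pass, with an adjusted p of 0.115, nor did HLA-DMB (2.99 against 3.11 FPKM). On the values the list's median log2 difference was 0.54 over 12 tested genes, and camera, limma's gene set test, gave an adjusted p of 7.77e-04 with its preset correlation and an adjusted p = 0.681 with an estimated correlation. On the values 0 members passed over all genes and 8 adjusted over the list alone, all higher. Leaving out the sh0 library reduced the 6 read-based calls to 1, HLA-DRA, with CIITA at an adjusted p of 0.0539 and HLA-DPB1 at 0.214, and 8 members rose and 1 fell without sh4. The controls con and sh0 themselves differed, with HLA-DRA at 109 and 85.3 FPKM. Many HLA genes have close paralogs, and how the authors' counting divided shared reads is not given in the sources used here.

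**Figure D3:**
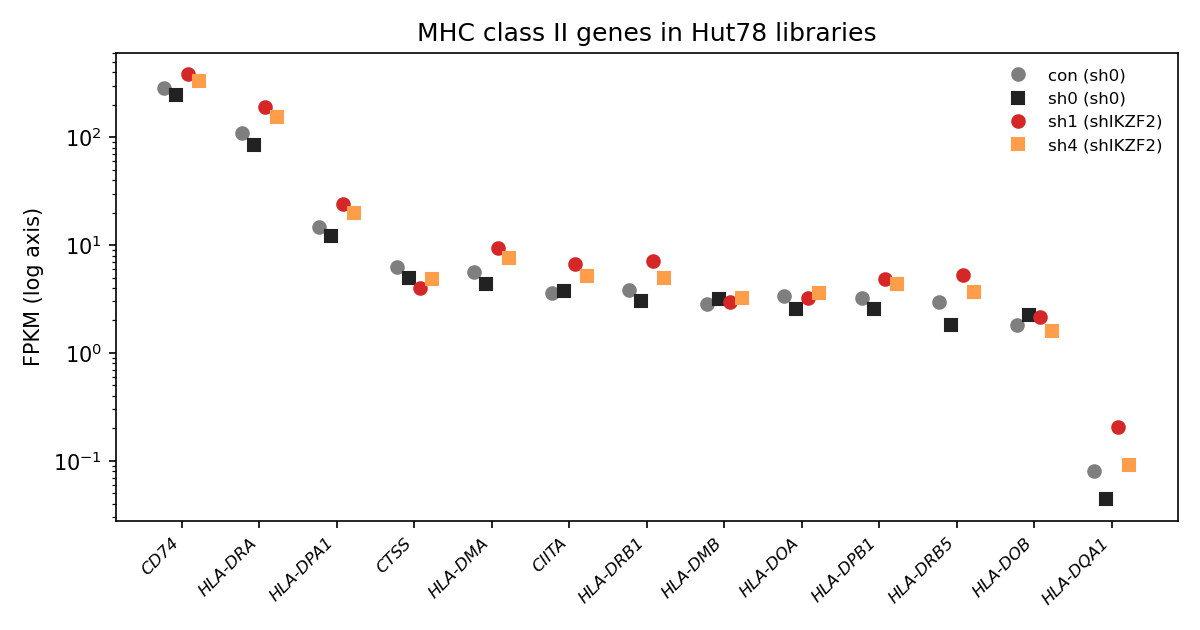
FPKM on a log axis of MHC class II genes with a value above 0 in every library, 1 point per library. HLA-DRA is at 109 and 85.3 FPKM in con and sh0 and at 192 and 153 in sh1 and sh4, and for HLA-DPA1, HLA-DMA, HLA-DPB1, CIITA and CD74 both shIKZF2 libraries also lie above both sh0 libraries, while for HLA-DMB they do not.

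Interferon-stimulated genes were higher as a list, with 4 members up and 1 down of 40 tested on reads, and 6 up and 2 down adjusted over the list alone. IFIT2 rose from 1.07 and 0.957 FPKM to 2.97 and 2.06, IFIT3 had a log2 change of 1.10, and XAF1 went from 6.87 ± 0.186 to 11.9 ± 1.96 FPKM. OAS2 fell by 0.32, and the classical members ISG15 (87.2 against 78.6 FPKM) and IFITM1 (92.5 against 87.7 FPKM) did not pass. Camera on the values gave a median log2 difference of 0.09 over 36 genes and an adjusted p of 0.0365, with an adjusted p = 0.681 with an estimated correlation. The call ended without the sh0 library (adjusted p = 0.468, median 0.06) and without sh1 (adjusted p = 0.160, median 0.04), the median was 0.16 without con or without sh4, and the read-based count of rises was 1 without the sh0 library, 3 without con or without sh1, and 8 without sh4. XAF1 passed each time, and OAS2 did not pass without con, sh0 or sh1 (adjusted p = 0.149 to 0.184).

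Among T cell genes the signalling list of the T cell receptor was lower, with 1 member up and 5 down of 30 tested on reads. CD3D fell by 0.38, LCK, the proximal receptor kinase, fell by 0.29, and GRAP2, UBASH3A and NFATC2 fell by 0.78, 0.52 and 0.42 on the log2 scale, whereas CD4 rose from 3.74 and 3.69 FPKM to 5.90 and 5.95. Adjusted over the list alone, 2 rose and 6 fell. CD3E (115 against 109 FPKM) and ZAP70 did not pass. On the values the list had a median of -0.07 and a camera adjusted p of 0.0452, an adjusted p = 0.681 with an estimated correlation, and the adjusted p lay between 0.0585 and 0.151 when any library was left out. Without con, without sh0 or without sh1 the 5 read-based falls became 1 in each case, and LCK, GRAP2 and UBASH3A passed in none of these (adjusted p = 0.0736 to 0.167), with UBASH3A at a log2 change of -0.32 without sh1. CD4 did not pass without sh0 (adjusted p = 0.0801).

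Genes typical of NK cells and CD8 T cells, several of which were transcribed in these libraries, were lower. Their median was -0.28 over 7 genes on the values (camera adjusted p = 6.13e-04, and adjusted p = 0.681 with an estimated correlation). Only NCR3 passed among 8 members tested on reads, going from 72.4 and 68.0 FPKM to 39.0 and 47.2, and 4 fell adjusted over the list alone (1 without con or without sh1, 6 without sh4). The Th1 and cytotoxic list had a median of -0.14 and an adjusted p of 0.0293 on the values, with an adjusted p = 0.681 with an estimated correlation. Of its 22 members tested on reads 1 rose and 2 fell, CTSW (cathepsin W) and RUNX3, and 7 fell and 4 rose adjusted over the list alone. Over all genes there were 0 rises and 1 fall without con or without sh1, 0 and 0 without sh0, and 3 and 6 without sh4, and over the list alone 2 to 3 falls and 1 to 2 rises without con, sh0 or sh1. That list did not pass camera on reads (adjusted p = 0.0597), nor on the values without con, sh0 or sh4. Skin homing and chemokine receptor genes had a median of -0.09 and an adjusted p of 0.0135 on the values, with an adjusted p = 0.681 with an estimated correlation. Their read-based falls were 2 of 15 members, SELPLG, which encodes the selectin ligand PSGL-1 (47.9 against 33.8 FPKM), and the integrin gene ITGA4, and 4 fell adjusted over the list alone. Without the sh0 library neither passed, and without sh1 the falls were 1, and without sh4 they were 4. The median on the values was -0.04 without sh1 and -0.14 without sh4. CCR4 (51.6 against 50.5 FPKM) did not differ by more than the spread.

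The Th2 list did not pass as a set (adjusted p = 0.108), although PTGDR2 and IL10 fell, the latter from 9.64 ± 0.326 to 5.99 ± 0.711 FPKM. Neither gene passed without the sh0 library, where their log2 changes were -1.05 and -0.69, against -1.09 and -0.72 with all libraries. The T cell activation list passed on reads (adjusted p = 0.00799, and adjusted p = 0.57 with an estimated correlation) but not in the main fit on the values (adjusted p = 0.322, and 0.0193 with the filter on reads or 0.0277 with no filter), with 4 of 26 members up and 1 down, and 7 up and 1 down adjusted over the list alone. The rises included the immediate early genes FOS and EGR1, from 0.424 and 0.421 to 2.05 and 1.08 FPKM and from 0.978 and 0.874 to 2.17 and 1.74 FPKM. The other rises, EGR2 and EGR3, rested on few reads. CD44 fell by 0.31, a call that ended without con, sh0 or sh1 (adjusted p = 0.0744 to 0.0948). The 4 rises became 1 without con, 0 without sh0, 2 without sh1 and 7 without sh4. That list did not pass without the sh0 library (adjusted p = 0.116) or with a filter of 5 CPM (adjusted p = 0.301). Secreted factors went both ways, with CSF2 up and LTB, from 459 and 436 to 271 and 330 FPKM, IL10 and IL16 down, and of these only LTB passed without the sh0 library, and CSF2 and IL16 did not pass without con (adjusted p = 0.0876 and 0.0729).

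Cytosolic ribosomal protein transcripts were lower as a group by a small amount. On the values 50 of 52 members lay lower, with a median of -0.12 and a camera adjusted p of 9.26e-12, and an adjusted p = 0.681 with an estimated correlation. By the read-based test 2 members fell, RPS18 and RPL4, and 20 adjusted over the list alone. Both counts became 0 without con or without sh1, and they were 3 and 36 without sh0 and 12 and 16 without sh4. Oxidative phosphorylation transcripts had a median of -0.10 over 33 genes (adjusted p = 6.89e-06, and adjusted p = 0.681 with an estimated correlation), with 0 members passing either test, alone or over all genes, and 6 falling in the read-based test without sh4. G2 and M phase genes had a median of -0.07 over 32 genes (adjusted p = 6.13e-04, and adjusted p = 0.681 with an estimated correlation). KIF20A, a mitotic kinesin gene, was the only one to fall over all genes, and 7 fell adjusted over the list alone on reads. Without sh0 or without sh1 these counts were 0 and 0, and without con 1 and 3, while KIF20A itself did not pass without con either (adjusted p = 0.109), and had a log2 change of -0.25 without sh1. Without sh4 6 members fell over all genes. The 15 mitochondrially encoded transcripts tested were higher on the values (median 0.18, adjusted p = 0.00197, and adjusted p = 0.681 with an estimated correlation), and 0 passed over all genes in either test (3 in the read-based test without con, 8 without sh4). Their share of reads was 2.76% in con, 2.40% in sh0, 3.03% in sh1 and 2.70% in sh4, so that the groups overlapped, and the call ended without the sh0 library (adjusted p = 0.336, median 0.08) and without sh1 (adjusted p = 0.289, median 0.09). The median was 0.28 without con and 0.30 without sh4.

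**Figure D4:**
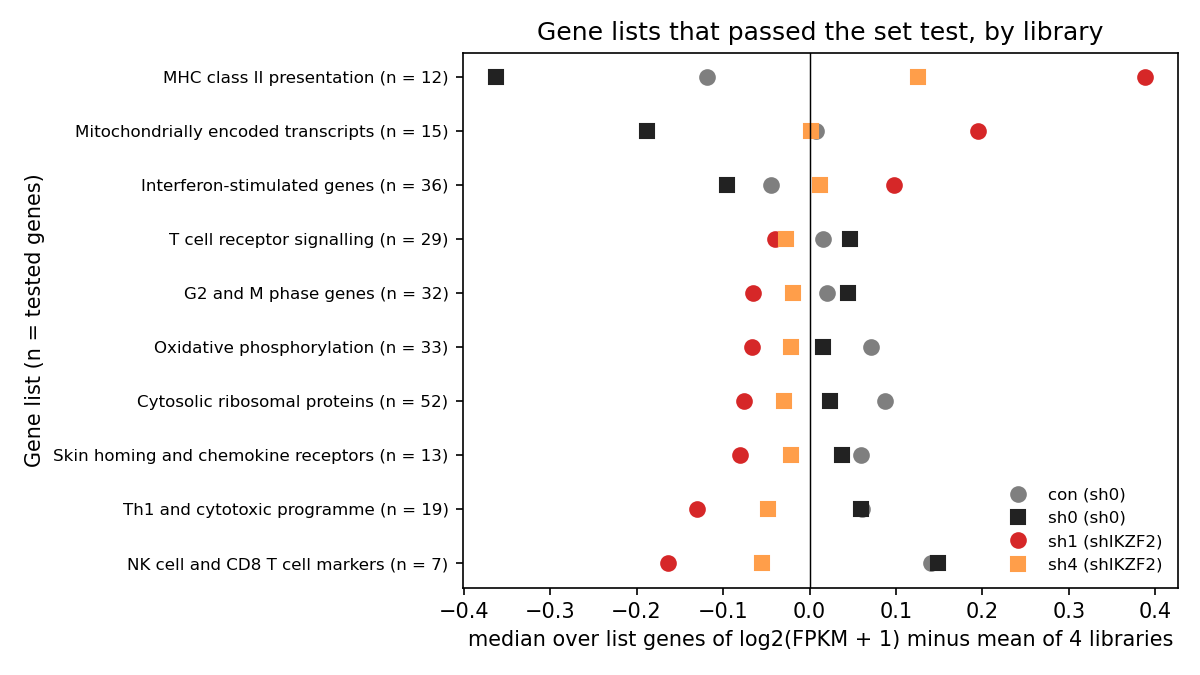
Median over the tested genes of each list of log2(FPKM + 1) minus the mean of the 4 libraries, for the 10 lists that passed camera with its preset correlation, 1 point per library. The MHC class II list lies at -0.12 and -0.36 in con and sh0 and at 0.39 and 0.13 in sh1 and sh4, and the lower lists spread over less than that.

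The remaining 28 of 38 lists tested on the values did not pass. Within the list of NuRD and Ikaros corepressor complexes, through which Ikaros proteins repress genes, GATAD2A (35.0 against 26.1 FPKM) and RBBP4 (31.3 against 22.9 FPKM) fell and CHD3 rose. Among genes reported as low in CTCL, BCL11B fell by 0.58, and TGFBR2 and TNFAIP3 rose by 0.43 and 0.49. Without the sh0 library all 6 of these genes lost the call (adjusted p = 0.0545 to 0.106), and without con CHD3 and TGFBR2 did (adjusted p = 0.193 and 0.127). Of the apoptosis genes the death receptor gene TNFRSF10B and BMF rose, and MCL1 fell by 0.39, and without sh0 none of the 3 passed (adjusted p = 0.0985 to 0.153). BMF and MCL1 also failed without con (0.119 and 0.0669), and MCL1 without sh1 (0.137, log2 change -0.25). The p53 target list passed only with fry (adjusted p = 0.0171), with a median of -0.01 and a mean of 0.09, so that median and test differ in sign. Of the marker lists of other cell types, the fibroblast list summed to 231, 216, 350 and 301 FPKM in con, sh0, sh1 and sh4. The NK and CD8 T cell list summed to 155, 151, 105.5 and 120 FPKM. The other marker lists summed to 48.07 FPKM or less in every library. Which cells made these transcripts was not tested. Fibroblast markers passed camera on reads (adjusted p = 0.044, and adjusted p = 0.57 with an estimated correlation) through COL6A1, from 109 and 102 to 189 and 158 FPKM, and COL6A2, the 2 of 7 members that rose. That list did not pass without the sh0 library (adjusted p = 0.057), with library totals only (0.0594), with the GC and length correction (0.0681) or with no filter (0.302), and COL6A2 did not pass without sh0 (adjusted p = 0.066). The hypoxia list passed on reads (adjusted p = 0.0498, and adjusted p = 0.57 with an estimated correlation), with VEGFA the 1 member to rise, and not without sh0 (adjusted p = 0.33) or without sh1 (adjusted p = 0.0749). It was also lost in all 5 other settings of the read-based fit (adjusted p = 0.0503 with upper-quartile factors to 0.112 with no filter), and VEGFA did not pass without con (adjusted p = 0.0658).

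Of 1490 GO terms in the deposited annotation, 16 passed camera on the values, 4 higher and 12 lower, and 0 with an estimated correlation (adjusted p = 0.98 for the top terms). The lower terms were headed by structural constituent of ribosome (253 genes, median -0.07, adjusted p = 4.52e-05) and cytoplasmic translation (61 genes, adjusted p = 1.18e-04). Among the higher terms were interferon-gamma-mediated signaling (49 genes, median 0.14, adjusted p = 0.00567) and interleukin-1-mediated signaling (32 genes, adjusted p = 0.0487). In the read-based fit 18 of 1792 terms passed, and 0 with an estimated correlation (smallest adjusted p = 0.948). Interleukin-1-mediated signaling did not pass camera in that fit (adjusted p = 0.0505).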

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

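The alternatives on recovered reads, the GC content and length correction and the filter on reads were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The planned tests on deposited counts were not run, as the file holds FPKM. The test on values passed 0 genes in each of 11 of its 12 alternatives (1038 to 2688 genes at an unadjusted p under 0.05 in its 10 other fits), and limma-voom on recovered reads passed 388. In the read-based test the count of 388 (187 higher, 201 lower) became 0 with no filter on low counts and 0 against a fold change of 1.5, with 0 higher and 0 lower in both. Leaving out 1 library gave 73 (without sh0) to 1308 (without sh4) genes, 27 to 636 higher and 46 to 672 lower, where the lone library of a group is assumed to vary like the others. Library totals only, upper-quartile factors, a filter of 5 CPM and the GC and length correction gave 343, 414, 335 and 399. The cause of these differences was not tested, but without a filter 27243 genes were tested in place of 15045.

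IKZF2 was lower in all 12 alternatives, from -0.49 to -0.62, and passed only with limma-voom on recovered reads (-0.60, adjusted p = 0.00429; range of adjusted p over the alternatives 0.00429 to 1). The count of lists that passed went from 10 to 0 with an estimated correlation and to 1 with fry. That 1 was the p53 target list, which is not among the 10 of the main test. Those 10 had adjusted p-values of 0.254 to 0.438 with fry, so none of them held. With 1 library left out, the count lay between 6 (without the sh0 library) and 10 (without con). The lists behind it changed. Without con the T cell receptor and Th1 lists left, and the hypoxia and cholesterol biosynthesis lists came in. Without sh1 the TGF-beta pathway list came in. The GO terms went from 16 to 0 with an estimated correlation. Over 130 alternatives for the 10 lists and 246 for the 25 genes chosen by rule from read-based values, 0 changed direction, and 32 and 73 lost the call. For the genes the direction was fixed in advance, since their groups do not overlap and the alternatives use the same libraries. At 2 libraries per group, an estimated correlation rests on 2 residual degrees of freedom.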

Other observations

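Every test here was chosen after the pattern it bears on was seen, the GC content and length correction included. What the correction and the comparison of neighbours on chromosome 11 should show was written before their results were seen, and what the other tests should show was written after. Of 27 genes of the T cell receptor loci in the read-based test (limma-voom, a set chosen after its values were seen), 2 rose and 2 fell. TRAC, the constant region of the alpha chain, was at 53.3 and 44.7 FPKM in con and sh0 and at 91.9 and 78.5 in sh1 and sh4 (log2 change 0.77 ± 0.10 SE, adjusted p = 0.00444), and the variable segment TRAV8-6 had a log2 change of 0.70 (adjusted p = 0.0161). TRGC1 and TRGV5 of the gamma locus fell by 0.70 and 0.92 (adjusted p = 0.00977 and 0.0127). TRBC2 of the beta locus, at 126 and 130 FPKM against 137 and 129, did not pass (adjusted p = 0.878). EGR2 and EGR3, transcription factors induced early after receptor stimulation, are members of the T cell activation list and were already among its 4 rises. They rose from 11 and 11 and from 5 and 2 reads to 54 and 40 and to 23 and 17 reads. Their corepressor NAB2 had a log2 change of 0.55 (adjusted p = 0.0324). IL4I1, a secreted amino acid oxidase gene, and the cytokine receptor gene IL6ST also rose, with log2 changes of 1.05 and 1.02 (adjusted p = 0.00543 and 0.00783). TRAV8-6, EGR2, EGR3 and NAB2 did not pass without the sh0 library (log2 changes of 0.57, 1.89, 1.74 and 0.47). EGR2, NAB2 and TRGV5 did not pass without con (1.92, 0.64 and -0.70), nor NAB2 without sh1 (0.39). EGR3 was not tested without sh1 or without sh4.

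Of the 388 genes of the read-based test, 352 (90.7%) changed more in sh1 than in sh4, against 62.4% of all genes tested, although IKZF2 itself differed little between them (log2 change -0.65 and -0.55). The median absolute log2 change was 0.59 in sh1 and 0.41 in sh4, and with separate controls (sh1 against con, sh4 against sh0, or the other way round) 81.2% and 85.0% changed more in sh1. A trend with GC content and the summed exon length of the gene does not account for this. After its removal from each library the share was 91.0%. Dilution by cells of another type in sh1 stays open. Marker sums of fibroblasts (350 against 301 FPKM), endothelial cells (4.41 against 3.93) and melanocytes (1.39 against 0.87) were higher in sh1 than in sh4. Those of keratinocytes, myeloid cells, B cells, and NK and CD8 T cells were lower. From sh4 to sh1, 6 genes of the T cell receptor complex differed by a median log2 of -0.0663 (-0.14 to 0.02). For the genes that fell the median was -0.19 (quartiles -0.29 and -0.11). Only CD3D lay under that upper quartile, with changes of -0.45 in sh1 and -0.31 in sh4. CD3D is itself among the genes that fell, so its place there was not independent. The others lay above the quartile, CD3E and CD247 only just, so the test cannot decide. The rises were not covered by that test. A difference between hairpins or cultures may also be the reason, a hypothesis that these labels leave untested.

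Ribosomal protein and oxidative phosphorylation transcripts, which are short, were lower in shIKZF2. A GC content and length trend may have produced this. After its removal the ribosomal protein median was -0.10, against -0.12 before (quartiles -0.13 and -0.06 after), and camera gave an adjusted p of 1.44e-11. The correction used the summed exon length of the gene, with a median of 3427 bases for the ribosomal protein list against 4476 for all genes tested. It did not use the length of the transcript, so it cannot exclude a trend with that length. Before the correction this list had an adjusted p = 0.681 with an estimated correlation. The same list differed between the controls, at 0.09 in con and 0.02 in sh0 relative to the mean of the libraries, against -0.08 and -0.03 in sh1 and sh4. A change of growth state and a drift between cultures both stay open as hypotheses.

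CCND1 and CTTN, among the largest rises, lie on chromosome 11 at 69641156 to 69654474 and 70398404 to 70436584 (hg38). More copies of that segment could have raised both. The 12 other protein-coding genes tested within 1 Mb had a median log2 change of -0.0075 (quartiles -0.11 and 0.06), and 0 passed. FADD and PPFIA1, which lie between the pair, had log2 changes of 0.03 and 0.29 (adjusted p = 0.944 and 0.061). MYEOV, upstream of CCND1 and at 0.049 to 0.26 FPKM, had the highest log2 change, 1.42 ± 0.55 SE, and did not pass (adjusted p = 0.222). The median argues against a gain of the whole segment and leaves regulation of the 2 genes open as a hypothesis.

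With 4 libraries there are 3 ways to split them into 2 groups of 2, too few for a share under 0.05. The real split gave 388 genes in the read-based test and 1835 at an unadjusted p under 0.05 on the values, and 1 of the 3 splits, the real one, gave as many in each test. The highest of the others gave 0 and 309. Each of the other splits puts 1 shIKZF2 and 1 sh0 library in each group, so a real difference widens the spread within its groups and lowers its count. Their counts on the values, 227 and 309, lie under the 605 expected by chance, so they are no measure of chance for the real split. Of 10451 protein-coding genes with 50 or more reads on average, 37 were at less than 0.5 times their sh4 level in sh1 and 1 at more than 2 times. Among the 388 were 0 of the 37. A gap of that size within the shIKZF2 group leaves the read-based test little room to call a gene, so this lack of overlap says nothing about the calls. Those 37 had a median GC content of 60.9%, against 47.9% in the others (permutation p = 0.0001, one-sided, the smallest that 10000 permutations can give), and PDXP, at 2.53, 3.40, 0.102 and 9.04 FPKM in con, sh0, sh1 and sh4, was the extreme.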
